A study of Rattus with 6 samples.

How the data were processed

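Polyadenylated RNA of H9C2 cells was sequenced in 6 libraries, 3 from cells given a control plasmid and 3 from cells given a plasmid for RBM25 overexpression. Per the labels' protocols, total RNA was treated with DNase, its integrity was checked on an agarose gel, and poly(A) RNA was captured on beads and made into strand-marked libraries that were sequenced as read pairs on an Illumina NovaSeq instrument. HISAT2, DESeq2 and the rat build mRatBN7.2 are named in the submitters' processing notes. Their versions, the program that counted reads, the gene annotation and whether counting used the strand are not given in the sources used here. Genes that overlap on opposite strands, and genes with a near-identical copy, are therefore uncertain.

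The deposited read counts are whole numbers per gene and were not normalized. They list 20742 genes, and none of these was at 0 in all 6 libraries. The deposited FPKM values were rounded to 2 decimals and list 20395 genes; how the authors defined gene length is not given in the sources used here. Gene identifiers in both tables are the prefix gene- followed by the symbol. The total of counted reads was 25543849 to 33130256 per library. No batch, day or culture of origin is stated, so p-values measure the spread between these libraries, which may be technical.

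The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 12882 genes. Libraries were scaled by TMM factors, which lay between 0.996 and 1.01, and a robust quasi-likelihood fit with group as its only term gave F-tests with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05, and at least 2-fold changed when its log2 fold change was also at least 1 in size. Fold changes are RBM25 plasmid over control plasmid, and the standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM scaled by the TMM factors and are given as mean ± SD over 3 libraries. For genes with few reads the ratio of summed reads, scaled by library size, was given with an exact 95% interval, which covers counting error only. Rbm25 was also compared by an exact permutation test of log2 CPM, whose smallest possible p with 3 libraries against 3 is 0.1.

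A total of 26 gene lists (pathways, splicing factors, muscle genes and markers of other cell types) were written before the data were examined. Of their members, 678 matched a symbol in the count table, 7 matched through synonyms in a RefSeq gene table of the assembly GRCr8, 13 mitochondrial genes were matched by hand to the table's shorter symbols, and 51 were not listed there. No coordinates are given, since that assembly differs from the files' build. The 22 lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 between members, and again with an estimated correlation. The fry test was run beside it. It asks whether a list's genes move one way on balance and compares them with no other genes. Its mixed form, which asks whether they move in either direction, is named where it is used. Members were counted past the threshold over all genes and, separately, adjusted over the list alone.

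The genes named in the text were chosen by a rule, also fixed before the data were examined. It takes Rbm25, then the 8 largest rises and up to 8 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a proper gene symbol, of which there were 8 and 5. For each list it adds up to 3 called members with the smallest p, or the 1 member with the smallest p where none was called. The rule gave 39 distinct genes, some of which are not reported here; genes outside it are marked as chosen after their values were seen.

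The test was tried on simulated counts drawn for the 12882 tested genes from the libraries' own means, depths and dispersions. For the comparison of RBM25 overexpression with control plasmid, edgeR recovered 67.2% of genes changed by 1.2-fold, 98.5% of those changed by 1.5-fold and 100% of those changed by 2-fold. Of its 202 calls, 20 were genes that had not been changed, a larger share than the nominal 5%. DESeq2 1.42.0 made 176 calls on the same counts, with 3 such genes. Correlation between genes was not among the inputs of the simulation. The camera results that follow therefore cannot show whether the preset correlation suits lists whose members vary together. The type I interferon list, for example, had an estimated correlation of 0.432 in the data. Camera called a simulated list of 30 shifted genes with the preset correlation (p = 1.37e-09) and with the estimated one (p = 0.00233), and did not call a list of 30 unchanged genes (p = 0.693 and 0.677).

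Replicates of a group were compared by chi-square tests of their counts. The statistic was 3.21 to 6.22 per degree of freedom for the 6 pairs, so no pair agreed within sampling noise and each library counted as 1 replicate. Alternatives changed the scaling (DESeq2 size factors, upper-quartile factors, library size alone), the filter, the test (DESeq2, limma-voom, limma-trend on the deposited FPKM values with a pseudocount of 1 or 0.1), the thresholds and the libraries included, and added a block for the replicate number. A correction for transcript length, implied by the ratio of counts to FPKM, was added after the data had been seen. Alternative splicing and RNA-binding data, which the study also set out to collect, were not analysed here.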

Results

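Gene expression was measured by RNA sequencing in H9C2 cells, a cell line from embryonic rat heart, that carried either a control plasmid (3 libraries) or a plasmid overexpressing RBM25 (3 libraries). RBM25 is an RNA-binding protein that works with the U1 snRNP in the choice of splice sites. The design asked which genes change their level when RBM25 is raised. Libraries held 25543849 to 33130256 counted reads, with a mean of 28451108 in the control group (SD 2.73e+06, n = 3) and of 30825263 in the RBM25 group (SD 2.83e+06, n = 3), and 16964 to 17428 genes had at least 1 read. The common biological coefficient of variation between replicates was 3.91%, so small changes could be detected.

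Rbm25 itself, on chromosome 6, was higher in each RBM25 library than in any control library, but the difference was small. Its level was 46.5 ± 2.46 CPM (SD, n = 3) with the control plasmid and 57.4 ± 2.31 CPM (SD, n = 3) with the RBM25 plasmid, a rise of 23.5%. The log2 fold change was 0.30 ± 0.047 (SE; edgeR adjusted p = 0.0011), and the exact permutation test gave p = 0.1, the smallest it allows. A far larger relative rise was seen for Rbm25l1, an RBM25-like gene on chromosome 10, which had 5 reads in the 3 control libraries together and 366 in the 3 RBM25 libraries. The ratio of its reads was 67.3 (95% interval 28.6 to 208), with a fitted log2 fold change of 5.97 ± 0.33 (SE; edgeR adjusted p = 7.27e-12). Rbm25l1 gained 3.88 CPM against 10.9 CPM for Rbm25, and both genes together went from 46.5 to 61.3 CPM, or 1.32-fold. Reads of Rbm25 can come from the plasmid as well as from the cell's own gene, and reads of such similar genes can be shared in counting, so the split between them is uncertain. The Rbm25 call was lost without control replicate 2 (log2 fold change 0.28, edgeR adjusted p = 0.0842) and on FPKM values (limma-trend adjusted p = 0.242).

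Of 12882 genes tested, 52 changed, 46 of them higher and 6 lower with RBM25 overexpression. Neither the small count nor the upward balance held without RBM25 replicate 3, where 352 genes changed, 196 higher and 156 lower, with all 52 kept. Apart from Rbm25l1, the genes that rose at least 2-fold were known interferon-inducible genes: the antiviral GTPase Mx1, Ifit1, the oligoadenylate synthetase family members Oas1b and Oasl, Apol9a, and the chemokine Cxcl10. The 1 gene that fell at least 2-fold was Cfb, complement factor B, which had 46 reads in the control libraries and 6 in the RBM25 libraries (ratio 0.12, 95% interval 0.0418 to 0.281; log2 fold change -2.98 ± 0.58, edgeR adjusted p = 0.0122). Of the 6 fits without 1 library, the Cfb call was kept in 3, with log2 fold changes from -3.95 to -2.40, and it was lost with DESeq2. The calls of Oas1b and Son were also kept in 3, and those of ND2 and Eif2b2 in 1. The remaining calls were modest, 42 of the 52 being below 1.5-fold.

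Among the largest rises, Apol9a went from 1.40 ± 0.159 to 6.40 ± 1.85 CPM (log2 fold change 2.17 ± 0.22 SE, edgeR adjusted p = 1.59e-04) and the non-coding RNA Lnc215 from a mean of 11.4 to 19.7 CPM (0.79 ± 0.084 SE, adjusted p = 7.71e-06). Postn, the matrix protein periostin, rose by a log2 fold change of 0.58 ± 0.11, Slfn4, of the schlafen family, by 0.48 ± 0.089, and the transcription factor gene Plag1 by 0.47 ± 0.087 (SE; adjusted p = 0.00922, 0.00922 and 0.00823). Among genes with a mean log2 CPM of at least 1, the falls were smaller. Tnip1, which encodes a partner of the NF-kB inhibitor A20, had a log2 fold change of -0.24 ± 0.044, Mvd, an enzyme of sterol synthesis, of -0.19 ± 0.033, and Eif2b2, a subunit of a translation initiation factor, of -0.15 ± 0.033 (SE; adjusted p = 0.00823, 0.0043 and 0.0399).

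All 52 called genes had no overlap between the groups, as did 16.2% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 1441 genes, against 644.1 expected by chance. The number of calls depended on single libraries: it was 5 without control replicate 2 and 21 without control replicate 3. It was 205 (149 higher, 56 lower) with no filter on low counts, and limma-trend on FPKM values called 0 genes, with 1035 at an unadjusted p under 0.05.

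**Figure D1:**
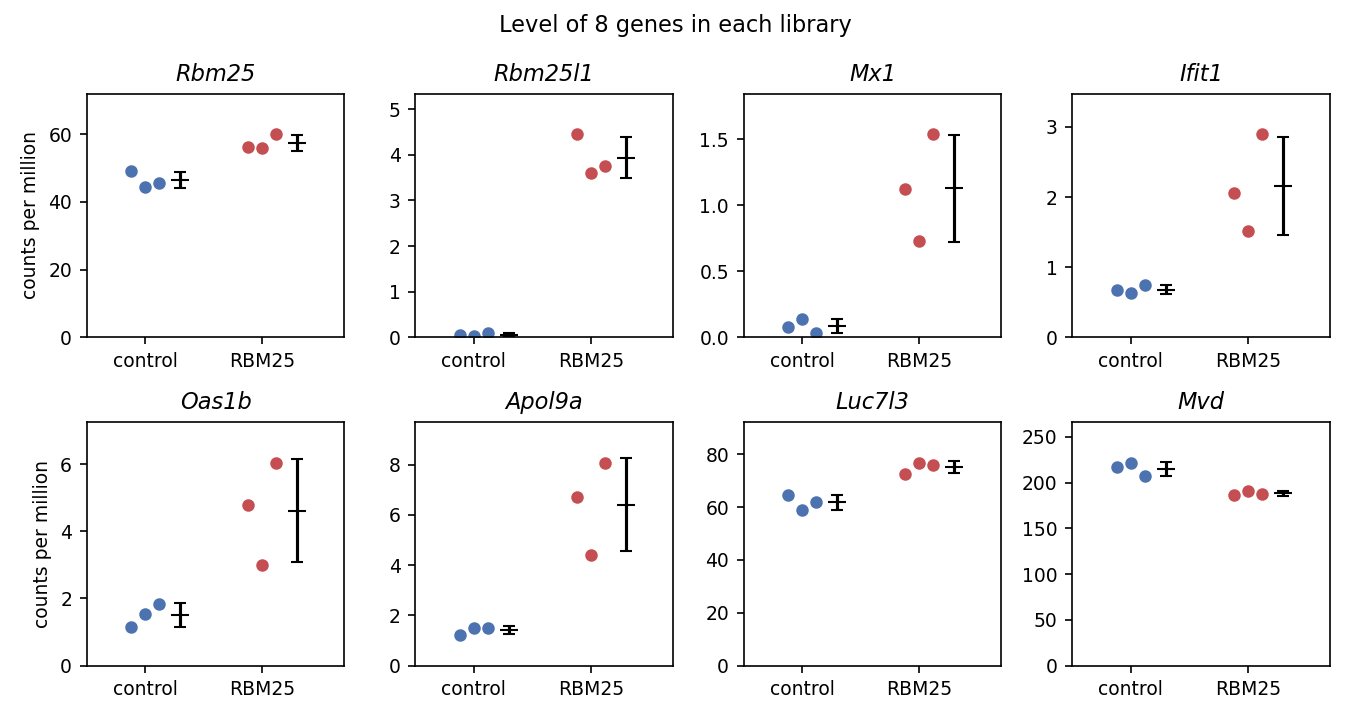
Level of 8 genes in each library, in CPM on linear axes from 0, with 1 point per library and a bar for mean ± SD (n = 3 per group). The mean of Rbm25 rose from 46.5 to 57.4 CPM. Rbm25l1 and the interferon-inducible genes had control means from near 0 to 1.50 CPM. Each of these genes was higher in each RBM25 library than in any control library.

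The type I interferon list had the smallest p by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.187, against 0.176 for the antigen presentation and sterol lists), and fry did not call it (adjusted p = 0.126). Of its 40 tested members, 5 rose past the all-gene threshold and none fell: Mx1, Ifit1, Oasl, Oas1b and, named here after its values were seen, Eif2ak2, the double-stranded RNA-activated kinase PKR. Mx1 had 7 reads in controls and 103 in RBM25 libraries (ratio 13.5, 95% interval 6.33 to 34.5; log2 fold change 3.70 ± 0.48, edgeR adjusted p = 1.59e-04). Ifit1 went from 0.679 ± 0.0592 to 2.16 ± 0.696 CPM (1.65 ± 0.26, adjusted p = 0.00144), Oasl from 1.10 ± 0.0521 to 2.98 ± 0.993 CPM (1.41 ± 0.23, adjusted p = 0.00184) and Oas1b from 1.50 ± 0.353 to 4.61 ± 1.53 CPM (1.59 ± 0.26, adjusted p = 0.0247). Eif2ak2 was more abundant and rose less (0.23 ± 0.042, adjusted p = 0.00729). Adjusted over the list alone, 14 members were higher and 1 was lower, and 37 of the 40 had a positive fold change, with a median of 0.26. The camera test against all other genes gave an adjusted p of 1.42e-20 with the preset correlation, and the adjusted p was 0.187 with an estimated correlation. The members' mean log2 difference from the control mean was 0.56, 0.34 and 0.86 in RBM25 replicates 1, 2 and 3, against -0.018 to 0.015 in the controls. Without control replicate 2 only 1 member was called, and without RBM25 replicate 2 there were 11.

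No shift of the cytokine genes in 1 direction was shown for their list, which was not tested against the interferon list. The mixed form of fry, open to changes either way, called the cytokine list (adjusted p = 0.00992). Of 15 tested inflammatory cytokines and chemokines, Cxcl10 rose (1.14 ± 0.309 to 2.56 ± 0.513 CPM; log2 fold change 1.16 ± 0.22, edgeR adjusted p = 0.00922) and 14 did not pass; adjusted over the list alone, 1 was higher and 1 lower. The list's median was -0.0029 and its mean 0.062, with a camera adjusted p of 0.958. The NF-kB pathway list was directed downward by camera (adjusted p = 0.0174, and 0.29 with an estimated correlation). Of its 29 members 1 was called (Tnip1, lower) by either adjustment, 8 had a positive fold change, and the median was -0.044. The groups overlapped in the list's mean log2 difference from the control mean, with RBM25 replicate 3 at 0.00023 and control replicate 1 at -0.027. Antigen processing and presentation went the opposite way to the interferon list, although many of its genes are also interferon-inducible. None of its 22 members was called over all genes, 2 were lower when adjusted over the list alone, and 18 had a negative fold change (median -0.097; camera adjusted p = 6.99e-04; adjusted p = 0.176 with an estimated correlation). Its top member, the class I gene RT1-CE5, was at 30.6 ± 1.32 and 26.5 ± 1.43 CPM (log2 fold change -0.20 ± 0.058, adjusted p = 0.123). Genes of that class resemble each other closely, so their separate counts are uncertain. Of 9 complement genes, Cfb fell and 8 did not pass (3 lower over the list alone; median -0.044; camera adjusted p = 0.0217; adjusted p = 0.23 with an estimated correlation).

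The splicing factor lists were directed upward by the camera test, but 1, 1 and 0 of their members passed the all-gene threshold. Among 21 tested SR proteins and their kinases, Son, a nuclear speckle protein, rose (log2 fold change 0.15 ± 0.034, edgeR adjusted p = 0.0341; 0.12 and 0.124 after a length correction, where it did not pass) and 20 did not pass; 6 were higher over the list alone and 18 had a positive fold change (median 0.044; camera adjusted p = 5.38e-05; adjusted p = 0.187 with an estimated correlation). In the list of U1 snRNP components and RBM25-associated factors, Luc7l3, a U1-associated protein, rose from 61.8 ± 2.84 to 75.0 ± 2.26 CPM (0.28 ± 0.041, adjusted p = 6.55e-04). The other 25 members did not pass, while 6 were higher over the list alone and 14 of 26 were positive (median 0.0020; camera adjusted p = 0.0174; adjusted p = 0.183 with an estimated correlation). Of 29 hnRNPs and other splicing regulators none was called, 3 were higher over the list alone, and the list reached a camera adjusted p of 0.0466 (median 0.024; adjusted p = 0.808 with an estimated correlation). Its top member Mbnl1 had a log2 fold change of 0.16 ± 0.038 (edgeR adjusted p = 0.0605). In the hnRNP list 17 members had a positive fold change. Its mean log2 difference from the control mean was highest in control replicate 1 (0.0715), above RBM25 replicates 1, 2 and 3 (0.0515, 0.0271 and 0.0060). Without control replicate 2, the U1 and hnRNP lists did not pass (camera adjusted p = 0.0592 and 0.489).

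Sterol biosynthesis and uptake genes tilted downward. Of 25 tested members, 3 fell past the all-gene threshold, among them Mvd (215 ± 7.66 to 188 ± 2.51 CPM), an enzyme of the mevalonate pathway, and 22 did not pass. Adjusted over the list alone, 15 fell. Only 1 member had a positive fold change, the median was -0.091, and 15 members had no overlap between the groups. The camera adjusted p was 2.35e-14 with the preset correlation and the adjusted p was 0.176 with an estimated correlation. The fry test also called this list (adjusted p = 0.0306). No member was called without control replicate 2, 1 without control replicate 1, 1 without RBM25 replicate 2 and 10 without RBM25 replicate 3.

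**Figure D2:**
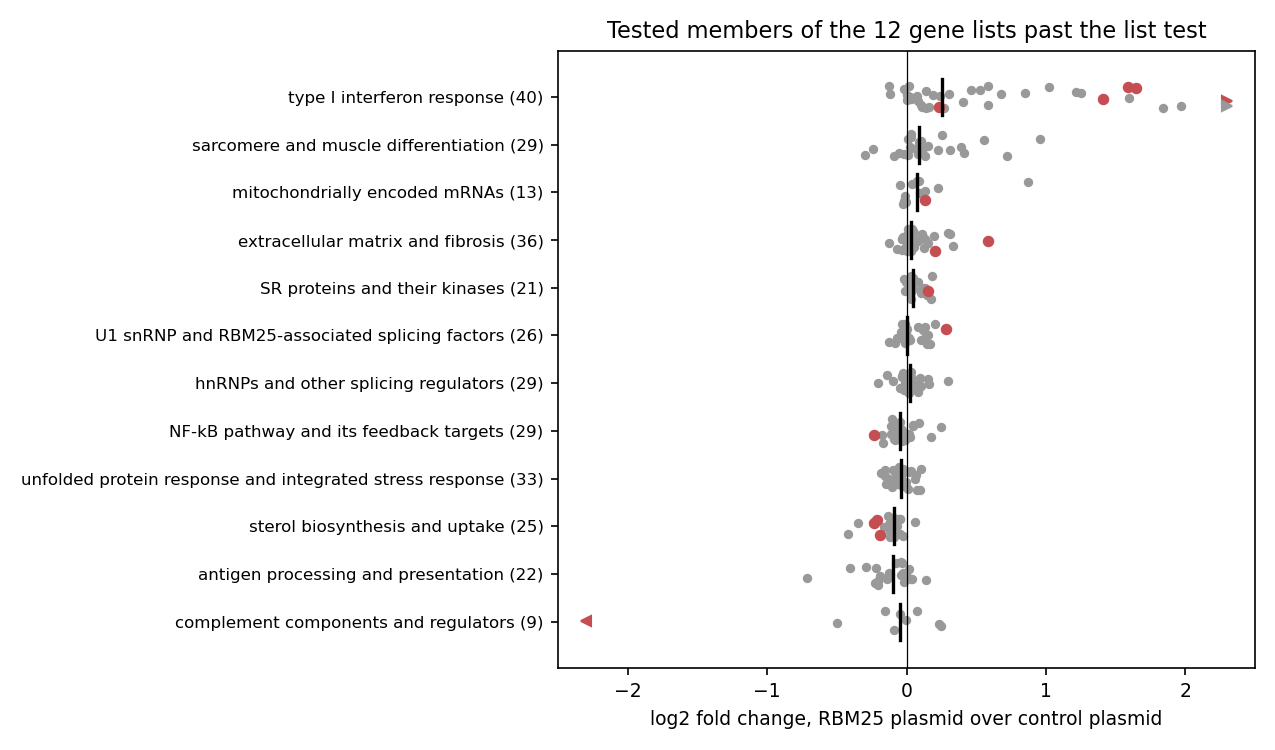
Log2 fold change of the tested members of the 12 lists past the camera test with preset correlation, 1 point per gene, red where the gene passed the all-gene threshold, with a black line at the list's median and the number of tested members in brackets. Triangles mark 3 genes beyond the axis limit (Mx1 at 3.70, Cfb at -2.98, and Dhx58); the interferon list spreads to the right and the sterol list lies to the left of 0 but for 1 member.

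The muscle, matrix and mitochondrial lists were directed upward by the camera test with the preset correlation. None of 29 sarcomere and muscle differentiation genes was called by either adjustment, yet 24 had a positive fold change (median 0.093; camera adjusted p = 6.50e-04; adjusted p = 0.183 with an estimated correlation); the top member Casq2, the calcium store protein calsequestrin, was at 329 ± 4.85 and 353 ± 2.18 CPM (log2 fold change 0.10 ± 0.030, edgeR adjusted p = 0.137). This list did not pass without RBM25 replicate 3 (camera adjusted p = 0.0885). Among 36 matrix and fibrosis genes, Tgfb2 (0.20 ± 0.035, adjusted p = 0.0045) and Postn rose, by either adjustment, and 34 did not pass (median 0.034; camera adjusted p = 0.0195; adjusted p = 0.183 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, ND2 rose from 3142 ± 103 to 3444 ± 125 CPM (0.13 ± 0.029, adjusted p = 0.0311) and 12 did not pass; 4 were higher over the list alone (median 0.073; camera adjusted p = 0.0174; adjusted p = 0.509 with an estimated correlation). Mitochondrial mRNAs took 4.93 ± 0.0671% of control reads and 5.06 ± 0.111% of RBM25 reads. Of the 13, 8 had a positive fold change. The mean log2 difference of this list from the control mean was 0.0656, -0.128 and 0.0619 in control replicates 1, 2 and 3. In RBM25 replicates 1, 2 and 3 it was 0.136, 0.201 and 0.0637, so the groups overlapped. Control replicate 2, the lowest, also had the fewest reads of the mitochondrial ND6 (893). In the list of cardiac stress and ion handling genes, the stress-responsive gene Ankrd1 rose from 1150 ± 29.0 to 1298 ± 13.2 CPM (0.17 ± 0.028, adjusted p = 0.00144), 16 of 17 members did not pass, and the list itself did not pass (camera adjusted p = 0.108).

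The unfolded protein and integrated stress response list was directed downward by camera (adjusted p = 0.0174, and 0.407 with an estimated correlation). None of its 33 members was called by either adjustment, 8 had a positive fold change, and the median was -0.043. The list's mean log2 difference from the control mean overlapped between the groups, with RBM25 replicate 3 at -0.0062 and control replicate 1 at -0.025. Its top member Phgdh, an enzyme of serine synthesis, had a log2 fold change of -0.095 ± 0.035 (edgeR adjusted p = 0.281). This list did not pass without control replicate 3 or RBM25 replicate 1 (camera adjusted p = 0.0806 and 0.213), and without RBM25 replicate 1 the NF-kB, complement, U1, hnRNP and mitochondrial lists did not pass either. The NF-kB and hnRNP lists also did not pass without control replicate 3 or RBM25 replicate 2, nor did the complement and mitochondrial lists without RBM25 replicate 2. No list passed camera with an estimated correlation, the smallest adjusted p being 0.176. The fry test called 4 lists, each with an adjusted p of 0.0306: antigen presentation, glycolysis and hypoxia, sterol synthesis, and matrix.

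The other lists did not pass. The camera adjusted p was 0.745 for cell cycle genes, 0.0899 for p53 targets and apoptosis, 0.609 for heat shock and oxidative stress, 0.873 for immediate early genes, 0.0521 for glycolysis and hypoxia, 0.535 for nuclear-encoded oxidative phosphorylation, 0.407 for cytosolic ribosomal proteins and 0.771 for fibroblast and mesenchymal markers. None of their members passed the all-gene threshold. Without RBM25 replicate 3 the p53 and glycolysis lists passed downward (camera adjusted p = 0.00341 and 0.0498), and without control replicate 2 the cardiac stress list passed upward (0.0430). Members with the smallest p of their list were Ccnd2 (log2 fold change -0.21, edgeR adjusted p = 0.222), Cdkn1a (-0.11, 0.138), Sod2 (-0.11, 0.317), Klf6 (0.21, 0.0706), Pkm (-0.098, 0.0799), Uqcrb (0.050, 0.623) and S100a4 (0.058, 0.548). Over the list alone, 1 immediate early gene was higher and 1 glycolysis gene was lower. Signs of mean, median and test were not the same for cell cycle genes (median -0.0014, mean 0.0019, test downward) and for immediate early genes (median -0.010, mean 0.013, test upward).

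Summed markers of other cell types differed between the groups by less than the replicate spread. The summed level of listed leukocyte and macrophage markers was 40.6 ± 1.90 CPM in controls and 40.9 ± 2.70 CPM with RBM25, that of endothelial markers 171 ± 4.40 and 169 ± 3.54 CPM, that of epithelial markers 813 ± 29.9 and 837 ± 74.7 CPM, and that of fibroblast markers 5608 ± 42.3 and 5616 ± 21.4 CPM (SD, n = 3). The leukocyte sum was mostly Cd14 and Cd3e, whose level would hide a small share of such cells. Likewise, the epithelial sum was mostly Krt7 (mean 786 of 813 CPM in controls), so it says little about the other epithelial markers. Too few of the leukocyte (3), endothelial (4) and epithelial (2) markers and of the nuclear-retained RNAs (1) could be tested as lists. Their top members were Cd3e (log2 fold change -0.098, edgeR adjusted p = 0.8), Eng (-0.063, 0.516), Krt7 (0.044, 0.885) and Gas5 (0.0096, 0.954).

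RBM25 replicate 3 stood apart from the other libraries of its group. Its counts differed from those of replicates 1 and 2 with a chi-square per degree of freedom of 6.22 and 4.79, against 3.21 between replicates 1 and 2. The mean log2 difference of the cell cycle list from the control mean was 0.099, 0.026 and -0.14 in RBM25 replicates 1, 2 and 3, and the same library had the highest mean of the interferon list. Without it the cell cycle list was called upward (camera adjusted p = 2.67e-05), and without RBM25 replicate 1 it was called downward (camera adjusted p = 4.12e-04). Both calls rest on the preset correlation of 0.01, whereas the estimate for this list over all libraries was 0.656.

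**Figure D3:**
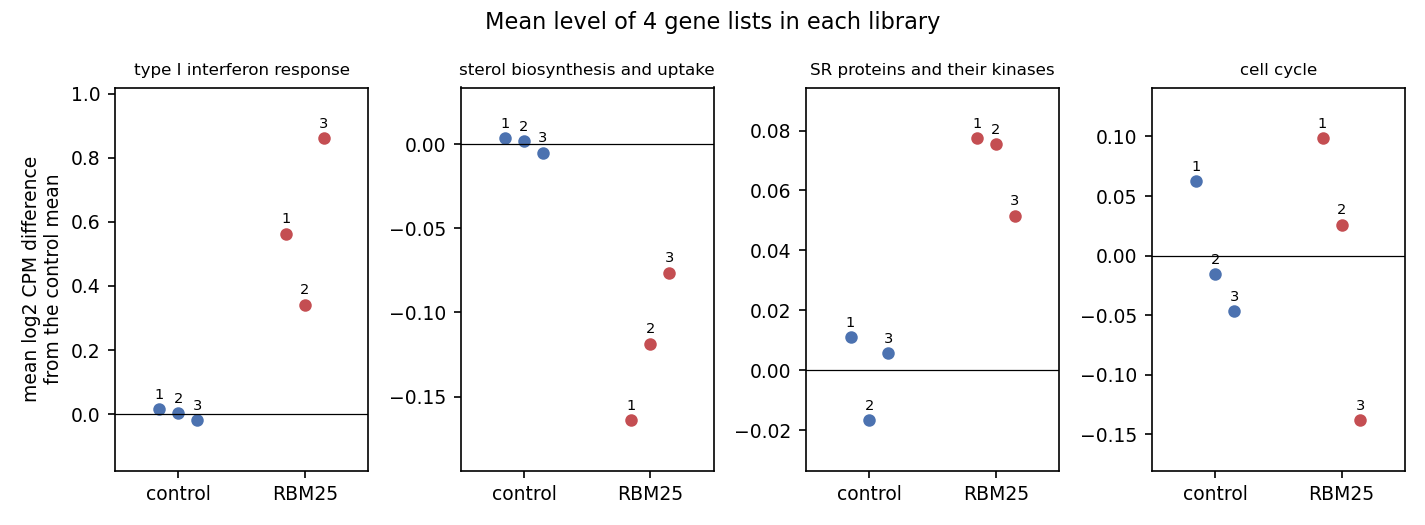
Mean log2 CPM difference of the tested members of 4 lists from the control mean, 1 point per library with its replicate number, on a separate vertical scale for each list. RBM25 libraries lie above the controls for the interferon list (0.34 to 0.86) and below them for the sterol list, while for the cell cycle list RBM25 replicate 3 (-0.14) lies below all other libraries.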

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

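The length correction was chosen after the results were seen, and all other alternatives were planned. The direction of each of the 52 called genes was the same in all 6 fits that left out 1 library, but only 5 calls (Rbm25l1, Lnc215, Mx1, Apol9a and LOC120094123) were kept in all of them and 14 in at least 5. Scaling changed little: DESeq2 size factors gave 54 calls, and upper-quartile factors and library size alone gave 64 each. The DESeq2 test gave 48 calls, 39 of them shared, and limma-voom 42, 38 of them shared. With libraries of 25543849 to 33130256 reads, genes near the filter limit the count of 2-fold changes, since most of those have few reads.

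With no filter on low counts, 205 genes changed (149 higher, 56 lower), 21 at least 2-fold (17 higher, 4 lower). With the stricter filter, 0 changed at least 2-fold (0 higher, 0 lower), because the genes concerned were no longer tested. DESeq2 called 0 genes at least 2-fold lower. With limma-trend on FPKM values, a pseudocount of 1 gave 0 genes changed (0 higher, 0 lower), 0 at least 2-fold, and an Rbm25 log2 fold change of 0.28 (adjusted p = 0.242); a pseudocount of 0.1 gave 0 throughout and 0.30 for Rbm25 (adjusted p = 0.244). With a pseudocount of 1 and no filter there were 5 (4 higher, 1 lower), 1 at least 2-fold (1 higher, 0 lower), and 0.28 for Rbm25 (adjusted p = 0.512). At an adjusted p under 0.01, 23 genes passed (21 higher, 2 lower), with 0 at least 2-fold lower. Tested against 1.5-fold, 3 genes passed (3 higher, 0 lower): Rbm25l1, Mx1 and Apol9a. Camera with an estimated correlation called 0 lists and fry called 4. The mixed form of fry called 12, the interferon list among them (adjusted p = 0.0414), but it gives no direction. The length correction gave 46 genes (37 higher, 9 lower) and 10 lists. Except where stated, the cause was not tested.

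Leaving out 1 library at a time gave 5 to 352 genes changed (5 to 196 higher, 0 to 156 lower), 3 to 19 at least 2-fold (3 to 13 higher, 0 to 6 lower), 7 to 14 lists and an Rbm25 log2 fold change of 0.27 to 0.35. The lowest count of genes was without control replicate 2, where Rbm25 had an adjusted p of 0.0842, and the highest was without RBM25 replicate 3, where all 52 calls were kept. The fewest lists, 7, were called without RBM25 replicate 1. The cell cycle list reversed to upward without RBM25 replicate 3, with an adjusted p of 2.67e-05, the lowest of a range that reached 0.489 downward without control replicate 2. The cause was not tested.

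A replicate block raised the genes changed to 436 (258 higher, 178 lower), 24 of them at least 2-fold (20 higher, 4 lower), with 12 lists and 0.31 for Rbm25. The numbers gave no clear pairing of the libraries: deviations of same-numbered libraries correlated at 0.226, -0.155 and 0.0940, and only number 1 correlated best with itself. With 3 libraries per group these correlations constrain each other and were not tested, so a pairing is not excluded. The cause of the higher count was not tested.

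Among 664 values of other named genes under the alternatives, 535 kept their side of the threshold, 106 lost the threshold and 23 gained it. Among 352 values of list tests the numbers were 302, 41 and 8, and 1, of the cell cycle list, reversed direction and passed. Direction was not compared where a gene or list passed in neither the main fit nor the alternative. Some of those values changed sign.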

Other observations

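The genes outside the naming rule were picked, and the tests of expected Rbm25l1 reads, of the gain ratio, of single libraries, of co-variation, of length and of the RNA binding motif family were chosen, after the results were seen. Some smaller rises are given here by gene, picked by hand from the calls and tested as no group. Srek1, a splicing regulator of the SR class, rose by a log2 fold change of 0.23, its partner Srek1ip1 by 0.30, the mRNA export factor Thoc2 by 0.29, Zfc3h1, a factor of nuclear RNA decay, by 0.32, and Nop58, a core protein of box C/D snoRNPs, by 0.19. The actin-binding Nexn rose by 0.27, Xirp1 by 0.37, Sorbs2 by 0.16, the kinase Rock2 by 0.20 and the microtubule motor gene Kif5b by 0.19. Each had an edgeR adjusted p under 0.05 and no overlap between the groups, and none reached 1.5-fold; after the length correction Srek1 (0.19), Zfc3h1 (0.30) and Sorbs2 (0.12) kept their direction but did not pass. Lnc215 (0.79) and LOC120094123 (0.70), 2 of the 5 calls kept in every fit without 1 library, are both on chromosome 8, and whether they share reads was not determined.

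The interferon genes Ifna1 and Ifnb1 had almost no reads, and other interferon genes were not looked up. Ifna1 had 1 read in the controls and 0 with RBM25, and Ifnb1 had 0 and 1. The receptor genes Ifnar1 (log2 fold change 0.0064, adjusted p = 0.973) and Ifnar2 (-0.041, adjusted p = 0.816) did not pass. Reads of the mitochondrial ND6 ranged from 893 to 7793 between libraries, and ribosomal RNA took 0.0925 to 0.203% of reads. Genes described as RNA binding motif proteins had an unadjusted camera p of 5.08e-05 as a family of 42. Without Rbm25 and Rbm25l1, the other 40 members had an unadjusted p of 0.0877 and a p of 0.347 adjusted over 20 families, so a shared rise beyond those genes was not shown. Adjusted over the family alone, Rbm39 (log2 fold change 0.15, adjusted p = 0.0185) and Rbm26 (0.20, adjusted p = 0.0243) were higher; over all genes neither passed (adjusted p = 0.0701 and 0.107).

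Rbm25l1 had 366 reads with RBM25 overexpression and 5 in controls. A plasmid transcript of the same sequence as the cell's own Rbm25 mRNA, some of its reads placed on the copy, was argued against: the control ratio predicted 6.72 reads, and at most 24. A change over the chromosome segment that holds the gene was also argued against, since the 10 nearest tested genes had a median log2 fold change of -0.049 (SD 0.125) and 0 of them were called. The order of these genes was taken from the assembly GRCr8, which differs from the files' build. A plasmid transcript that differs in sequence, from another species or recoded, could place part of its reads on the copy. The mean gain in Rbm25l1 was 0.356 of the mean gain in Rbm25. In single RBM25 libraries the Rbm25l1 level, with no control level subtracted, was 0.277 to 0.456 of the gain in Rbm25. No read positions or plasmid sequence were at hand. Such a transcript therefore cannot be told apart from a rise of the cell's own Rbm25l1, which remains open and untested.

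For the rise of the type I interferon list, one RBM25 library alone was argued against, since the lowest RBM25 library was 0.34 above the control mean, with a control SD of 0.0166. White blood cells in the RBM25 cultures stay open. The 11 leukocyte markers too low to test went from 66 to 101 reads, a gain that was 0.00598 of the list's gain. However, the list's summed level (1070 ± 16.5 and 1123 ± 68.9 CPM, SD, n = 3) gained less than its spread, so this ratio decides nothing. The most read marker, Cd68, had 7, 8 and 9 reads in the controls and 17, 19 and 9 in RBM25 replicates 1, 2 and 3. Laptm5, Coro1a, Aif1 and Mrc1 had at most 1 read in any library. Such counts are too low to settle the question. Members varying together between libraries for reasons other than the plasmid were not excluded. The estimated correlation was 0.432, and camera with it gave an adjusted p of 0.187. The list's means lay close together in the controls (-0.018 to 0.015) and further apart in the RBM25 libraries (0.34 to 0.86). With 3 libraries per group these values do not decide the question. An effect of RBM25 on these genes, and a response to the plasmid or its transcripts as foreign nucleic acid, both remain open and were not tested.

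The genes that rose tilted toward longer transcripts: 71.7% of the 46 were longer than the median tested gene, with a median of 5509 nt against 3599 nt. The 6 that fell had a median of 2287 nt. Fold change and length correlated across all genes (Spearman rho 0.106). A trend of counts on transcript length as the whole cause was argued against for most, since after it was removed (rho -0.010) 36 of the 46 were still past the threshold, with a median log2 fold change of 0.28 after 0.29. The 10 lost calls went from a median of 0.27 (SD 0.14) to 0.25 (SD 0.13), with adjusted p from 0.0502 to 0.223 after it. The fold change was lower after the correction in all 10 and the SE larger in 5, so for these calls a part played by length stays open; 5 of the 6 lower calls were kept. An effect of RBM25 on long transcripts was not tested, and base composition was not tested for lack of a genome.

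The 6 libraries can be split into groups of 3 in 10 ways. A count of genes changed as large as the real 52 was reached by 2 of them, the real one included, the highest other being 68 with control 1 and RBM25 1 and 2 on one side. A count of 2-fold changes as large as the real 8 was reached by 1, the highest other being 1, and a count of lists as large as the real 12 by 1, the highest other being 8. Of the other splits, 6 called the interferon list (smallest adjusted p = 3.46e-13) and 5 the sterol list (1.90e-06); each of them still sets 2 RBM25 libraries against 1. With 10 splits, no share under 0.05 can be reached, so chance is neither excluded nor shown for any of these counts.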
